A study of Rattus norvegicus with 20 samples.

How the data were processed

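The series measured total RNA from primary cultures of neonatal rat heart cells (cardiomyocytes, the contracting cells of heart muscle), untreated or treated with diclofenac. Per the labels, RNA was taken with Trizol, amplified with a low-input linear amplification kit, labelled with the dye Cy3 and hybridised to 4-array Agilent rat slides. There were 20 arrays in 7 groups, taken from the sample titles: untreated (n = 2) and diclofenac at reference concentration 1, 1/5 or 1/25 for 6 h or 24 h (n = 3 each). The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

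Per the file headers, the scanner software was Agilent Feature Extraction 9.5.3.1 and its values are in the unit intensity: brightness after subtraction of background and detrending across the slide, not scaled between arrays. The deposited table of the series holds a ratio: checked against the scanner values, it is each array's processed signal divided by the array's median and then by the mean of the 2 untreated arrays. The scanner values were used for the main results and the deposited table as an alternative. Positions are those in the array files, on build rn3, and the reference table of gene names was used only to update symbols. Symbols came from a matching accession for 10811 probes, a matching symbol for 5562 and a synonym for 3717, and 20922 probes kept the name in their file.

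Processed signals were put on the log2 scale, and the array's 75th percentile over non-control spots was subtracted. Spots marked as outliers or non-uniform by the scanner software were left out (120 to 271 of 43379 on an array), saturated spots were kept, and replicate spots of a probe were averaged on the log2 scale. A probe was kept when it was well above background on every array of at least 1 group, which kept 35065 of 41012 probes. The brightest kept probe stood for a gene, which gave 30495 genes. Of 3714 genes with several kept probes, 0 had probes called in both directions. At most 89 probes passed the threshold in a comparison, so this says little about agreement between the probes of a gene. Where a gene was not well above background on any array of a group, the fold was given only as a bound beside the log2 change, against the lowest signal that was well above background on the array. No bound was computed for the interaction. Where both groups were at that level no fold was given.

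Groups were compared with limma 3.58.1 in R 4.3.3, with a mean for each group over all 20 arrays, empirical Bayes moderation of the spread and two-sided tests adjusted by the Benjamini-Hochberg method over the genes of a comparison (threshold 0.05). There were 14 comparisons: each treated group with the untreated cultures, adjacent concentrations at one time, 24 h with 6 h at one concentration, and the interaction of concentration and time. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Single arrays of one group were compared first, and no 2 arrays held the same values. The numbers of the replicates gave no clear sign that arrays were paired across groups. Among 57 pairs with the same number the median correlation of the arrays' deviations from their group means was -0.04, against 0.04 for other numbers. It ran from -0.76 to 0.64, with 12 pairs over 0.1. Differences in signal between arrays enter these deviations as well, so pairing is not excluded.

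The 24 gene lists cover contractile, cardiac stress, calcium handling and ion channel, fatty acid oxidation, oxidative phosphorylation, integrated stress response, NRF2, heat shock, p53, apoptosis, cell cycle, prostanoid, NF-kB, interferon, immediate early, cholesterol, drug metabolism, hypoxia and glycolysis, and proteasome genes, and markers of fibroblasts, smooth muscle, endothelium, leukocytes and erythroid cells. They were tested in the 6 comparisons with untreated cultures by camera with a preset correlation of 0.01, on the 30259 genes with a value on every array. Camera with an estimated correlation and fry stood beside it, and adjustment ran over all 144 tests. Where an alternative used weights, slide as a random block or a robust fit, the list test ran on the moderated statistics. With the replicate block or slide as a fixed block, camera ran with the block as a term of the fit. List medians were also computed with members at their bounds.

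The named genes follow a rule. For concentration 1 at 6 h and 24 h against untreated cultures it takes the 10 highest and 10 lowest changes among genes past the threshold with all treated arrays on one side of both untreated arrays, a change of at least 1 (log2) and a symbol that is not a locus or clone identifier. The other comparisons take the 3 highest and 3 lowest. Where none passed, the 2 with the smallest p in each direction were given as values. For each list at concentration 1 it takes up to 3 passing members or, where none passed, the 2 with the largest change. Ptgs1, Ptgs2, Nppa, Nppb, Myh6 and Myh7 were always given. Some list members that the rule takes are not reported here. Names of expressed sequence tags were treated as clone identifiers, which the rule does not spell out. LOC291521, AI168935, TC566397 and the alternatives of genes just short of the threshold were chosen after values were seen. The groups, comparisons, filter, lists, naming rule and first set of alternatives were fixed before the data were examined.

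Those alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, the mean of a gene's probes, a trended and robust fit, a fit of only the groups compared, slide as a random or fixed block or within 1 slide, the replicate block, the deposited table, and each array left out in turn. Chosen after the data were seen were leaving the third array of 1/5 for 24 h out of the shared fit, array weights by 2 methods, a correction of each array for probe GC content, scan day as a block, and 2 further fits within a slide and 1 within a scan day. The slides and scan days come from the file headers. With a slide or day as a fixed block only some comparisons can be estimated.

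The steps were tested on simulated data, with 50 genes shifted at each size among 30259. For concentration 1 at 6 h against untreated cultures 0, 20, 58 and 94% of genes shifted by 1, 2, 3 and 4 (log2) were recovered. At 24 h the shares were 0, 14, 70 and 82%, and for 24 h against 6 h at concentration 1 they were 4, 44, 80 and 92%. False calls were 5, 8 and 4 of 30059 genes. The simulated noise was independent between arrays and, for a gene, of equal size on every array. The real arrays differed in signal and shared a main axis of variation, so these shares and false calls may not hold for them. Random probe sets numbered 10000 and permutations 100000. Control spots were left out of every comparison.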

Results

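Gene expression was measured on 20 1-colour rat arrays carrying RNA from primary cultures of neonatal rat heart cells. The labels name untreated cultures and cultures given diclofenac, a non-steroidal anti-inflammatory drug that inhibits the cyclooxygenases encoded by Ptgs1 and Ptgs2. Untreated cultures had 2 arrays, although the series text gives 3 replicates for each group. Diclofenac at reference concentration 1, 1/5 or 1/25, for 6 h or 24 h, had 3 arrays in each of 6 groups. The series set out to compare treated with untreated cultures over these concentrations and times. The labels give neither the molar value of the reference concentration nor the time of the untreated cultures, so in every comparison with them treatment and time in culture cannot be told apart.

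Each array read 43379 spots. The share of spots well above background ran from 64.1% on the third array of 1/5 for 24 h to 88.2%, with a median of 83.7%. Other low shares were 72.4% on the first array of 1/25 for 24 h, 75.1% on the second of 1/25 for 6 h and 76.5% on the first of 1/5 for 24 h. The 75th percentile of the scanner signal ran from 3165 to 21937, and 4.93 to 10.8% of spots were saturated. Arrays of one group correlated across probes with a median Pearson r of 0.966 and a lowest of 0.784, against a median of 0.953 for arrays of different groups (across probes, which are not independent replicates). The number of arrays limits the precision: the median SE of a log2 change was 0.552 against the untreated cultures and 0.493 for 3 arrays against 3.

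The first principal axis of the 20 arrays held 50.3% of the variance over 30259 genes. Within groups, an array's place on this axis followed its share of spots well above background, with Pearson r = -0.883 (permutation p = 0.00189) and Spearman rho = -0.782 (permutation p = 0.00109). Without the 2 arrays whose deviation of the share from their group mean lay farthest from the median deviation, r was -0.802 (permutation p = 0.00841). The group means behind the deviations still included these 2 arrays. Of the axis' variance a share of 0.565 lay between the 7 groups, and among the treated arrays a share of 0.404 between 6 h and 24 h.

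**Figure D1:**
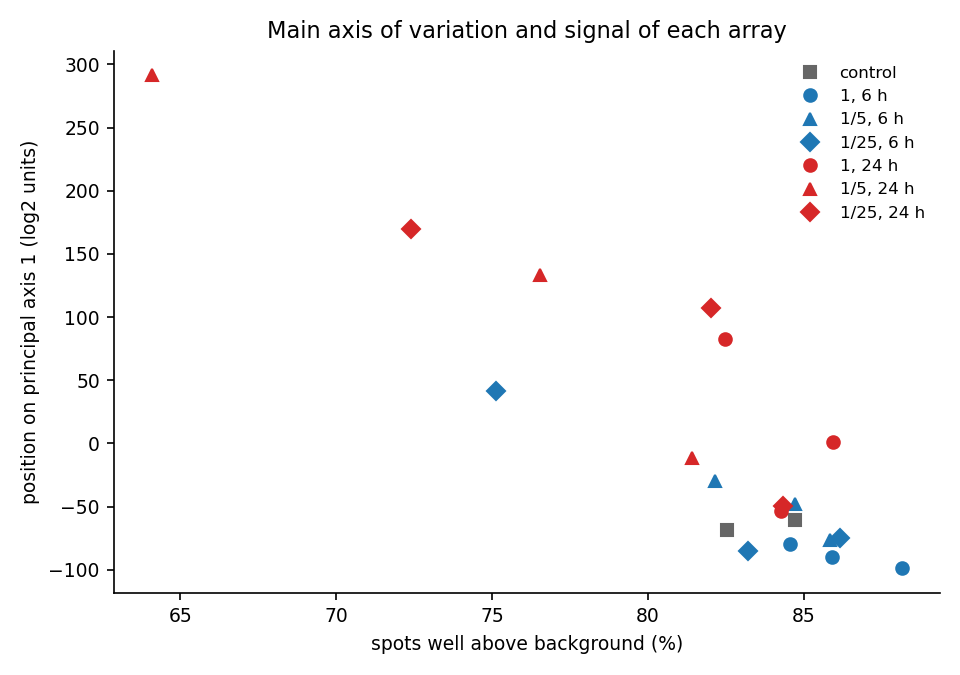
Position on principal axis 1 (log2 units) against the share of spots well above background (%) for the 20 arrays, 1 point per array, with the colour giving the time and the shape the concentration. The array with the lowest share, 64.1%, is the third of 1/5 for 24 h.

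Rhag and LOC291521 rose after 6 h at concentration 1. Rhag, which encodes the Rhesus-associated glycoprotein of red blood cells, had a normalized log2 signal of -3.56 ± 0.92 (SD, n = 3) against -7.96 ± 0.16 (SD, n = 2) in untreated cultures, a change of 4.40 ± 0.63 (SE, adjusted p = 0.0363). LOC291521, described in the files as similar to spindlin-like protein 2, had -3.82 ± 0.74 (SD, n = 3) against -8.06 ± 0.18 (SD, n = 2), a change of 4.24 ± 0.50 (SE, adjusted p = 0.00577). Neither gene was well above background in the untreated cultures, so the signals were at least 5.55-fold higher for Rhag and at least 4.65-fold higher for LOC291521. The Rhag probe lies on chromosome 9 from 15943788 to 15944670 and that of LOC291521 on unplaced sequence (chromosome Un) from 15913891 to 15913950 (build rn3, as for all positions below).

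These were the 2 genes of 30495 past the threshold against untreated cultures, both higher, and 454 genes had an unadjusted p under 0.05. The change exceeded 2 on the log2 scale upward in 178 genes and downward in 10. Of the 178, 84 (47.2%) were well above background on neither untreated array, against 1.74% of all genes. The filter on dim probes keeps such a gene only where it was bright in a treated group, so both shares depend in part on the filter. Picking genes by a rise of more than 2 over the untreated cultures also favours genes that are dim there. The gap between the 2 shares follows in part from this choice and is no result by itself. LOC291521 lies outside the naming rule and was chosen after its values were seen. Without the first or the second untreated array neither call was made, with adjusted p of 0.546 and 0.930 for Rhag and 0.184 and 0.366 for LOC291521. Rhag was also not called without the second or the third treated array (adjusted p = 0.213 and 0.225), and read -0.16 with no filter on dim probes, where another probe stood for the gene. On the slide that holds 2 arrays of each group the changes were 4.07 for Rhag (adjusted p = 0.337) and 4.41 for LOC291521 (adjusted p = 0.243). With slide as a fixed block they were 4.07 (adjusted p = 0.401) and 4.41 (adjusted p = 0.0437). Over all 21 alternatives the adjusted p ran from 0.000458 to 1.00 for Rhag and from 3.77e-05 to 1.00 for LOC291521.

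**Figure D2:**
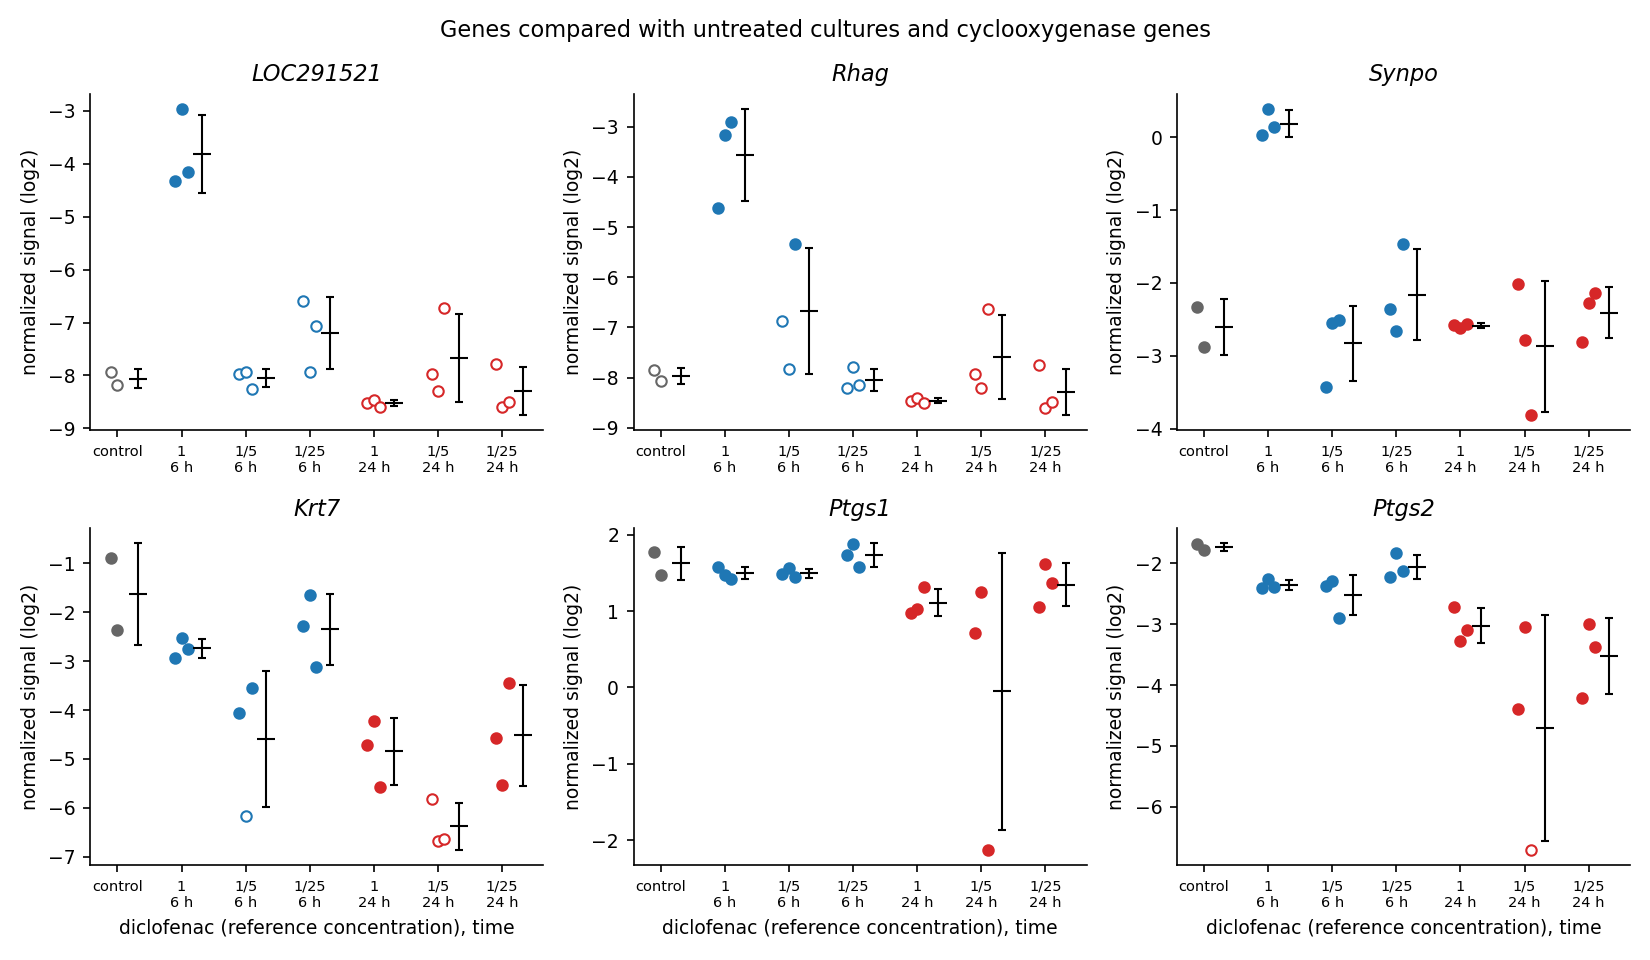
Normalized signal (log2) of 6 genes on each array by group, with filled points well above background, open points not, and black lines with bars the mean ± SD (n = 2 untreated, n = 3 otherwise). LOC291521 lay at -3.82 at concentration 1 for 6 h against -8.06 in untreated cultures, and Ptgs1 at 1.49 against 1.62.

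After 6 h at concentration 1/5, no gene passed the threshold with limma, and 335 genes had an unadjusted p under 0.05. The genes with the smallest p are given as values. They were Or2y13, an olfactory receptor gene, at 2.78 ± 0.75 (log2 change, SE), Dnajc6, which encodes the co-chaperone auxilin, at 3.08 ± 0.86, Acot8, a peroxisomal acyl-CoA thioesterase, at -3.26 ± 0.77, and Krt7, a keratin of simple epithelia, at -2.95 ± 0.73 (adjusted p = 1.00 each). Or2y13 was not well above background in untreated cultures and was at least 2.99-fold higher. With slide as a fixed block 2 genes passed.

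After 6 h at concentration 1/25, limma called 0 genes as well, with 343 at an unadjusted p under 0.05. Ccn2, which encodes connective tissue growth factor, stood at 1.36 ± 0.42 (SD, n = 3) against 0.07 ± 0.31 (SD, n = 2), a change of 1.29 ± 0.44 (SE, adjusted p = 1.00). The other smallest p values belonged to Fdxacb1 at 2.06 ± 0.61 (SE), at least 3.90-fold higher, Plb1, a phospholipase B gene, at -2.10 ± 0.47 and Zfp865 at -1.63 ± 0.38 (adjusted p = 1.00 each). No slide or scan day held both this group and untreated arrays, so concentration and slide cannot be told apart here. The same holds for the 3 groups at 24 h below.

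AI168935, an expressed sequence tag from rat kidney, fell after 24 h at concentration 1. Its signal was -7.92 ± 0.61 (SD, n = 3) against -3.94 ± 0.49 (SD, n = 2), a change of -3.99 ± 0.55 (SE, adjusted p = 0.0447), and at least 5.79-fold lower because no treated array read it well above background. The probe lies on chromosome 10 from 78465959 to 78466018. Igtp, an interferon-induced GTPase gene, stood at -4.54 ± 0.70 (SD, n = 3) against -7.86 ± 0.08 (SD, n = 2), a change of 3.33 ± 0.49 (SE, adjusted p = 0.0512) and at least 2.83-fold. Adam5, of the disintegrin and metalloprotease family, had a change of -2.40 ± 0.37 with the same adjusted p. Kirrel3, a cell adhesion gene, was at 2.44 ± 0.43 and Plb1 at -2.59 ± 0.47, at least 5.73-fold lower (adjusted p = 0.158 each).

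AI168935 was the 1 gene past the threshold, and 1399 genes had an unadjusted p under 0.05. It lies outside the naming rule and was chosen after its values were seen. The call was lost with any 1 of the 5 arrays left out. Its adjusted p was then 0.235 and 0.574 without the first and second untreated array and 0.111, 0.0571 and 0.137 without the first, second and the third treated array. Over its 18 alternatives the adjusted p ran from 2.66e-06 to 0.574. Without the third array of 1/5 for 24 h, which had the lowest signal, 24 genes passed, and Igtp and Adam5 were among them (adjusted p = 0.0107 and 0.0164). The range over their alternatives was 1.39e-05 to 0.716 for Igtp and 3.43e-07 to 0.818 for Adam5. With quantile normalization the 1 gene that passed was higher. The median change of all genes was -0.11, -0.13 and -0.13 at 24 h for concentrations 1, 1/5 and 1/25 against untreated cultures, and the changes given here stand beside these shifts.

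The 24 gene lists fixed in advance were tested at concentration 1 for both times, and none passed with camera (adjusted p of 0.492 to 0.992 at 6 h and 0.492 to 0.971 at 24 h). No single member passed over all genes at either time, and adjusted over the list alone 0 passed at 6 h and 1, Flt1, at 24 h. Members named in the next paragraphs are therefore given as values (log2 change ± SE), up to 2 for each list and time.

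Contractile and sarcomere genes, which build the contractile apparatus, had 19 of 22 members measured, with median changes of -0.18 at 6 h and -0.16 at 24 h (-0.21 and -0.30 with members at their bounds) and 5 and 5 members above 0. At 6 h the members farthest from 0 were Actn2 at 0.72 ± 0.93 and Myh6 at -0.68 ± 0.93, and at 24 h Ckm at -1.61 ± 0.57 and Actn2 at -1.35 ± 0.93. Cardiac stress and fetal genes, re-expressed in stressed heart muscle, had 12 of 13 members measured, with median changes of -0.16 at 6 h and -0.24 at 24 h (-0.15 and -0.20 with members at their bounds) and 3 and 5 members above 0. Acta1 at 0.53 ± 1.09 and Nppa at -0.37 ± 0.85 lay farthest from 0 at 6 h, and Postn at -1.76 ± 0.89 and Ccn2 at 0.77 ± 0.44 at 24 h. Calcium handling and ion channel genes, which set excitation and contraction, had 24 of 24 members measured, with median changes of -0.05 at 6 h and -0.23 at 24 h (-0.05 and -0.27 with members at their bounds) and 10 and 4 members above 0. Kcnq1 at 0.66 ± 0.96 and Cacna1g at 0.47 ± 0.51 lay farthest from 0 at 6 h, and Sln at -1.60 ± 0.68 and Kcnq1 at 1.54 ± 0.96 at 24 h. Fatty acid oxidation and PPAR target genes, of mitochondrial fat use, had 22 of 27 members measured, with median changes of 0.10 at 6 h and 0.03 at 24 h (0.10 and 0.04 with members at their bounds) and 15 and 12 members above 0. Fabp3 at -0.51 ± 0.67 and Cd36 at 0.43 ± 0.47 lay farthest from 0 at 6 h, and Ucp2 at -1.55 ± 1.22 and Ech1 at 0.89 ± 0.37 at 24 h. Oxidative phosphorylation genes, of the respiratory chain, had 26 of 27 members measured, with median changes of -0.05 at 6 h and -0.12 at 24 h (-0.05 and -0.12 with members at their bounds) and 8 and 10 members above 0. Cycs at -0.37 ± 0.48 and Atp5f1a at 0.29 ± 1.20 lay farthest from 0 at 6 h, and Atp5f1a at -1.76 ± 1.20 and Ndufs1 at -1.12 ± 0.64 at 24 h.

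Integrated stress response and ER stress genes had 20 of 26 members measured, with median changes of 0.00 at 6 h and -0.14 at 24 h (0.00 and -0.19 with members at their bounds) and 10 and 8 members above 0. At 6 h the members farthest from 0 were Sesn2 at 0.63 ± 0.65 and Hspa5 at -0.48 ± 0.61, and at 24 h Pdia4 at -1.85 ± 1.30 and Sesn2 at -1.23 ± 0.65. NRF2 oxidative stress genes had 24 of 25 members measured, with median changes of 0.03 at 6 h and -0.05 at 24 h (0.04 and -0.06 with members at their bounds) and 15 and 9 members above 0. Nqo1 at 0.84 ± 1.14 and Gclc at -0.79 ± 0.88 lay farthest from 0 at 6 h, and Gsta1 at 1.72 ± 0.71 and Cat at -1.63 ± 1.34 at 24 h. Heat shock genes had 16 of 18 members measured, with median changes of -0.10 at 6 h and -0.12 at 24 h (-0.09 and -0.12 with members at their bounds) and 5 and 7 members above 0. Hspa1l at -0.84 ± 0.46 and Hspb7 at 0.55 ± 0.57 lay farthest from 0 at 6 h, and Hsph1 at -1.77 ± 1.01 and Hspa1a at -1.20 ± 0.76 at 24 h. P53 target and DNA damage genes had 18 of 20 members measured, with median changes of -0.01 at 6 h and -0.23 at 24 h (0.00 and -0.24 with members at their bounds) and 8 and 5 members above 0. Perp at 2.11 ± 0.89 (at least 4.25-fold higher) and Xpc at 1.06 ± 0.63 lay farthest from 0 at 6 h, and Sesn1 at -1.78 ± 1.01 and Perp at 1.46 ± 0.89 (at least 2.72-fold higher) at 24 h. Apoptosis regulator genes had 23 of 27 members measured, with median changes of 0.03 at 6 h and -0.16 at 24 h (0.03 and -0.20 with members at their bounds) and 12 and 6 members above 0. Bcl2l11 at -1.09 ± 0.68 and Xiap at 0.75 ± 1.04 lay farthest from 0 at 6 h, and Xiap at -1.77 ± 1.04 and Bcl2l11 at -1.37 ± 0.68 at 24 h. Cell cycle genes had 30 of 32 members measured, with median changes of 0.12 at 6 h and -0.25 at 24 h (0.13 and -0.25 with members at their bounds) and 19 and 9 members above 0. Aurkb at 0.79 ± 0.46 and Mki67 at 0.75 ± 0.43 lay farthest from 0 at 6 h, and Mcm5 at -2.28 ± 1.41 and Kif11 at -1.50 ± 0.73 at 24 h. Proteasome subunit genes had 24 of 25 members measured, with median changes of -0.06 at 6 h and -0.08 at 24 h (-0.05 and -0.07 with members at their bounds) and 7 and 10 members above 0. Psmd1 at -0.49 ± 0.58 and Psmd11 at 0.41 ± 0.88 lay farthest from 0 at 6 h, and Psmd11 at -0.69 ± 0.88 and Psmc6 at 0.48 ± 0.71 at 24 h.

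Prostanoid synthesis and receptor genes had 17 of 24 members measured, with median changes of -0.04 at 6 h and -0.22 at 24 h (-0.04 and -0.22 with members at their bounds) and 5 and 5 members above 0. At 6 h the members farthest from 0 were Ptger1 at 1.05 ± 0.91 and Ptgfr at -0.81 ± 0.45, and at 24 h Ptger1 at -1.72 ± 0.91 and Tbxa2r at -1.42 ± 1.01. Inflammatory cytokine and NF-kB target genes had 18 of 24 members measured, with median changes of -0.03 at 6 h and -0.18 at 24 h (-0.09 and -0.19 with members at their bounds) and 7 and 5 members above 0. Ccl20 at -1.16 ± 0.81 and Ccl2 at -1.09 ± 0.91 lay farthest from 0 at 6 h, and Ccl2 at -2.23 ± 0.91 and Ccl20 at -1.71 ± 0.81 at 24 h. Interferon-stimulated genes had 17 of 18 members measured, with median changes of 0.01 at 6 h and -0.01 at 24 h (0.01 and -0.01 with members at their bounds) and 9 and 8 members above 0. Irf7 at 1.54 ± 0.89 and Tap1 at 0.86 ± 0.88 lay farthest from 0 at 6 h, and Stat2 at -1.33 ± 0.85 and Rsad2 at 1.28 ± 0.44 at 24 h. Immediate early genes had 21 of 21 members measured, with median changes of 0.00 at 6 h and -0.19 at 24 h (-0.01 and -0.21 with members at their bounds) and 10 and 6 members above 0. Junb at 1.01 ± 0.56 (at least 1.32-fold higher) and Fosb at 0.76 ± 0.51 lay farthest from 0 at 6 h, and Junb at 0.93 ± 0.56 (at least 1.24-fold higher) and Fosl1 at -0.90 ± 0.54 at 24 h. Cholesterol biosynthesis genes had 21 of 24 members measured, with median changes of 0.10 at 6 h and -0.12 at 24 h (0.16 and -0.14 with members at their bounds) and 14 and 8 members above 0. The member farthest from 0 at 24 h was Srebf2 at -1.32 ± 0.72 (at least 1.98-fold lower). Drug metabolism and transport genes had 19 of 26 members measured, with median changes of 0.19 at 6 h and 0.07 at 24 h (0.20 and 0.07 with members at their bounds) and 14 and 12 members above 0. Cyp2e1 at 1.31 ± 0.68 and Cyp2c11 at 1.04 ± 0.93 lay farthest from 0 at 6 h, and Cyp1a1 at -2.75 ± 1.30 and Cyp2j3 at 1.25 ± 0.54 at 24 h. Hypoxia and glycolysis genes had 23 of 24 members measured, with median changes of 0.00 at 6 h and -0.11 at 24 h (0.10 and -0.10 with members at their bounds) and 11 and 8 members above 0. Pfkfb3 at 0.93 ± 0.58 and Hk2 at 0.75 ± 0.44 lay farthest from 0 at 6 h, and Ldha at -1.50 ± 1.19 and Pfkfb3 at 1.20 ± 0.58 at 24 h.

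Fibroblast and extracellular matrix markers had 19 of 20 members measured, with median changes of -0.04 at 6 h and -0.28 at 24 h (0.03 and -0.40 with members at their bounds) and 8 and 2 members above 0. At 6 h the members farthest from 0 were Dcn at 0.55 ± 0.54 and Col5a1 at 0.50 ± 0.60, and at 24 h Col5a1 at -1.86 ± 0.60 and Postn at -1.76 ± 0.89. Smooth muscle markers had 8 of 10 members measured, with median changes of 0.08 at 6 h and -0.23 at 24 h (0.08 and -0.23 with members at their bounds) and 4 and 1 members above 0. Myh11 at 0.64 ± 0.59 and Mylk at 0.59 ± 0.56 lay farthest from 0 at 6 h, and Cnn1 at -1.73 ± 0.67 and Smtn at -1.01 ± 0.59 at 24 h. Endothelial markers had 11 of 12 members measured, with median changes of 0.17 at 6 h and 0.04 at 24 h (0.17 and 0.04 with members at their bounds) and 8 and 6 members above 0. Tek at 0.90 ± 0.66 and Cdh5 at 0.87 ± 0.52 lay farthest from 0 at 6 h, and Flt1 at -2.29 ± 0.51 and Cdh5 at -0.93 ± 0.52 at 24 h. Leukocyte and macrophage markers had 14 of 16 members measured, with median changes of -0.03 at 6 h and -0.37 at 24 h (-0.03 and -0.37 with members at their bounds) and 6 and 2 members above 0. Aif1 at 0.75 ± 0.66 and Cd163 at 0.58 ± 0.34 lay farthest from 0 at 6 h, and Ptprc at 1.29 ± 0.41 and C1qc at -1.05 ± 0.70 at 24 h. Erythroid markers had 4 of 11 members measured, with median changes of 0.12 at 6 h and -0.56 at 24 h (0.12 and -0.56 with members at their bounds) and 2 and 1 members above 0. Slc4a1 at 0.91 ± 0.46 and Ahsp at -0.66 ± 0.58 lay farthest from 0 at 6 h, and Ahsp at -1.51 ± 0.58 and Slc4a1 at -1.01 ± 0.46 at 24 h. Flt1 passed adjusted over the list alone and not over all genes (adjusted p = 0.309).

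Median, mean and test of a list differed in sign in 47 of the 144 tests of lists over the 6 treated groups. At concentration 1 for 6 h these were the integrated stress response, NRF2, p53 target, apoptosis, interferon, immediate early, hypoxia, fibroblast and leukocyte lists, and at concentration 1 for 24 h the NRF2, endothelial, interferon, cholesterol and proteasome lists. Over all 144 tests camera and fry called 0, camera with an estimated correlation called 0, and 11 had an unadjusted camera p under 0.05. The mixed test of fry, which asks whether members change in either direction, called 1, the endothelial markers at 1/5 for 24 h (adjusted p = 0.0146). Of the 11, at 1/5 for 6 h the contractile (median -0.19), prostanoid (-0.14), NF-kB (-0.20), interferon (-0.32) and endothelial (-0.21) lists were on the lower side and at 1/25 for 6 h the cardiac stress list (0.05) on the higher side, with adjusted p of 0.462 to 0.492. The other 5 belong to 1/5 and 1/25 for 24 h. Over all genes 2 members passed in the 144 tests, and 33 adjusted over the list alone.

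After 24 h at concentration 1/5, Akr1c15, an aldo-keto reductase gene, rose from -2.51 ± 0.36 (SD, n = 2) to 0.68 ± 0.97 (SD, n = 3), by 3.20 ± 0.44 on the log2 scale (SE, adjusted p = 0.00974). Ppp3cc, which encodes a calcineurin catalytic subunit, rose by 3.71 ± 0.71 (adjusted p = 0.0475), at least 6.32-fold, and Eepd1 by 3.01 ± 0.48 (adjusted p = 0.0169). Krt7 fell by 4.74 (SE 0.73, adjusted p = 0.0143) from -1.63 ± 1.04 (SD, n = 2) to -6.37 ± 0.48 (SD, n = 3), at least 14.8-fold. Clec14a, an endothelial C-type lectin gene, fell by 3.89 (SE 0.69, adjusted p = 0.0295) and Garin1b fell by 3.70 (SE 0.61, adjusted p = 0.0196). The probes lie on chromosome 17 from 77352210 to 77352269 (Akr1c15), chromosome 15 from 50656932 to 50661852 (Ppp3cc), chromosome 8 from 25286167 to 25286226 (Eepd1), chromosome 7 from 140252063 to 140252122 (Krt7), chromosome 6 from 78855278 to 78855337 (Clec14a) and chromosome 4 from 56473413 to 56473472 (Garin1b).

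In all, 56 genes passed, 20 higher and 36 lower, and 9276 had an unadjusted p under 0.05. Genes whose probes had a GC content under 40% had a median change of 0.42, and those over 50% a median of -0.37. The probes of Akr1c15, Ppp3cc and Eepd1 held 36.7, 31.7 and 26.7% GC, and those of Krt7, Clec14a and Garin1b 45.0, 45.0 and 51.7%. After GC correction of each array 84 genes passed, 23 higher. Eepd1 was then at 1.93 ± 0.40 (SE, adjusted p = 0.0542) and lost its call through the smaller change. The other 5 kept theirs, Akr1c15 at 2.88 (adjusted p = 0.00523), Ppp3cc at 3.23 (adjusted p = 0.0477), Krt7 at -4.52 (adjusted p = 0.0182), Clec14a at -3.67 (adjusted p = 0.0487) and Garin1b at -3.51 (adjusted p = 0.0244). The count was 0 without either untreated array, 48 without the first treated array, 10783 without the second and 73 without the third. It was 81 with 45 higher after quantile normalization, and 0 when only the arrays of these groups were in the fit. Each of the 6 named genes was lost without either untreated array. Without the first and the second, the adjusted p was 0.121 and 0.181 for Akr1c15, 0.410 and 0.249 for Ppp3cc, 0.183 and 0.286 for Eepd1, 0.352 and 0.104 for Krt7, 0.352 and 0.318 for Clec14a, and 0.352 and 0.195 for Garin1b. Over all alternatives of the 6 genes it ran from 0.000104 (Akr1c15) to 1.00.

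Among the gene lists, members of several moved both ways at concentration 1/5 for 24 h. Over all genes, 2 members passed: Hspa1l, of the 70-kDa heat shock family, at -2.66 (adjusted p = 0.0234) and Flt1, a VEGF receptor gene of endothelium, at -3.27 (adjusted p = 0.0147). Hspa1l, Flt1 and Hsph1, named below, were each well above background on only 1 of the 3 treated arrays, so the sizes of their changes are uncertain. Adjusted over the list alone, 4 NRF2 oxidative stress genes were higher (Gclm 2.11, Me1 1.25, Gsta1 2.77, Sod1 1.20) and 3 lower (Osgin1 -1.68, Gsr -2.11, Gpx2 -1.24). Of the hypoxia and glycolysis genes 4 were higher (Pfkp, Adm, Eno1, Pkm) and 4 lower (Hk2, Ldha, Pgk1, Tpi1), again adjusted over the list alone. Adm and Eno1 were saturated in both groups. These values come from a group in which 2 of the 3 arrays had 64.1 and 76.5% of spots well above background, and the SD of its arrays reached 2.60 for Tpi1 and 3.29 for Pgk1. The tests use a spread shared over all groups, which gave an SE of 0.95 for Tpi1 and 1.21 for Pgk1. For members that varied this much between the arrays of this group, the p-values may understate its spread. They also stand beside the shift with GC content given above: the probes held 15.0% GC for Gclm and 38.3% for Gsta1, higher, and 55.0% each for Osgin1 and Tnni1, lower, but also 55.0% for Tie1, higher, and 35.0% for Kif11, lower. The other members past the threshold in this way were Kdr at 1.39 and Tie1 at 1.79 (higher, beside Flt1 lower, among 11 endothelial markers), and Tnni1 at -2.65, Postn at -4.43, Aldh1l2 at -2.26, Hspa1l, Hsph1 at -3.23, Kif11 at -2.61 (at least 1.97-fold), Nusap1 at -1.52, Ptgs2 at -2.98, Col5a1 at -2.49 and Slc4a1 at -2.30 (lower). All 8 measured smooth muscle markers lay below 0, with a median of -1.21 (camera adjusted p = 0.462, and 0.918 with an estimated correlation).

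After 24 h at concentration 1/25, AI168935 again fell, from -3.94 ± 0.49 (SD, n = 2) to -8.05 ± 0.31 (SD, n = 3), a change of -4.12 ± 0.55 (SE, adjusted p = 0.0296) and at least 4.52-fold lower. Akr1c15 had a change of 2.01 ± 0.44 (adjusted p = 0.183), Olfml1 of 2.39 ± 0.54 (adjusted p = 0.193), Celf4, an RNA-binding protein gene, of -2.32 ± 0.41 (adjusted p = 0.160) and Adam5 of -2.08 ± 0.37 (adjusted p = 0.160). Of the proteasome subunit genes, 21 of 24 lay above 0, with a median of 0.31 (0.30 with members at their bounds), and of the oxidative phosphorylation genes 20 of 26, with a median of 0.41. Heat shock genes had a median of 0.36 and cell cycle genes of -0.43. These medians stand beside a shift with GC content, with a median change of 0.29 for genes whose probes held under 40% GC and -0.42 for those over 50%, and 1 of the 3 arrays had 72.4% of spots well above background. These 4 lists did not pass with camera (adjusted p = 0.462 for the first 2 and 0.492 for the others, and 0.918 with an estimated correlation). The proteasome list passed with array weights by REML (adjusted p = 0.0371) and with GC correction (adjusted p = 0.0198). Ccn2 at 1.64 (higher), Postn at -2.66 and Flt1 at -2.26 (lower) passed only when adjusted over the list alone.

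AI168935 was the 1 gene past the threshold, with 4053 at an unadjusted p under 0.05. It was lost without the first or second untreated array (adjusted p = 0.168 and 0.531) and without the first or the third treated array (0.0900 and 0.0663), with a range over its 18 alternatives of 2.05e-06 to 0.531. The count was 0 without either untreated array or without the first or the third treated array, 617 without the second treated array, 79 (37 higher) without the third array of 1/5 for 24 h and 6, all higher, after quantile normalization.

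Ptgs1 and Ptgs2, which encode the cyclooxygenases that diclofenac inhibits, did not pass over all genes in any comparison, and Ptgs2 passed at 1/5 for 24 h when adjusted over the prostanoid list alone. At 6 h Ptgs1 lay at -0.13, -0.13 and 0.11 (SE 0.63) for concentrations 1, 1/5 and 1/25 relative to untreated cultures, and at 24 h at -0.52, -1.68 and -0.28. Ptgs2 lay at -0.62, -0.79 and -0.32 (SE 0.68) at 6 h and at -1.29, -2.98 and -1.80 at 24 h, with a smallest adjusted p of 0.0940 at 1/5. The natriuretic peptide gene Nppa lay between -0.87 and 0.41 (SE 0.85) over the 6 groups and Nppb between -0.40 and 0.29 (SE 0.31). Nppb was saturated in every group except 1/5 for 24 h, which limits what its values can show. The myosin heavy chain genes Myh6 and Myh7 lay at 2.04 ± 0.93 (SE, adjusted p = 0.152) and 2.10 ± 0.81 (SE, adjusted p = 0.130) at 1/5 for 24 h, and between -0.68 and 0.89 and between -0.19 and 1.21 in the other groups.

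Between concentrations at 6 h, Synpo, which encodes the actin-associated protein synaptopodin, was higher at 1 than at 1/5, at 0.19 ± 0.18 (SD, n = 3) against -2.83 ± 0.52 (SD, n = 3), a difference of 3.02 ± 0.43 (SE, adjusted p = 0.0317). In untreated cultures it was at -2.61 ± 0.39 (SD, n = 2). LOC291521 was also higher, by 4.23 ± 0.45 (SE, adjusted p = 0.00123), at least 5.03-fold. The Synpo probe lies on chromosome 18 from 56625830 to 56625889. These were the 2 genes past the threshold, with 856 at an unadjusted p under 0.05. Synpo was lost with any 1 of the 6 arrays left out. Its adjusted p was then 0.0544, 0.179 and 0.158 without the first, second and the third array of concentration 1 and 0.142, 0.133 and 0.0761 without those of 1/5. On the slide with 1 array of concentration 1 and 3 of 1/5, the differences were 2.97 for Synpo (adjusted p = 0.381) and 3.89 for LOC291521 (adjusted p = 0.177), and 0 genes passed. With 1 array on one side, which has no spread of its own, this fit has little power and the lost calls show little. With slide as a fixed block 7 genes passed, 1 higher and 6 lower, and neither Synpo (adjusted p = 0.412) nor LOC291521 (adjusted p = 0.120) was among them. The adjusted p over 22 alternatives ran from 9.39e-08 to 0.412 for Synpo and from 1.06e-07 to 0.754 for LOC291521.

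Between 1/5 and 1/25 at 6 h limma called 0 genes, and 844 had an unadjusted p under 0.05. Tec, a tyrosine kinase gene, was at 1.60 ± 0.35 (SE), Ceacam1, a cell adhesion gene, at 1.51 ± 0.36 (at least 1.46-fold higher), Ccn2 at -1.53 ± 0.39 and Cspg4 at -1.33 ± 0.34 (adjusted p = 1.00 each). Without the third array of 1/25, 16 genes passed.

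Between 1 and 1/5 at 24 h limma also called 0 genes, with 6561 at an unadjusted p under 0.05. Igtp was at 3.06 ± 0.44 (SE, adjusted p = 0.0741), at least 1.99-fold higher, and Chrnb1, which encodes the muscle nicotinic receptor beta subunit, at 2.33 ± 0.39 (at least 1.47-fold higher). Ccr2, a chemokine receptor gene, was at -2.70 ± 0.53 and Cblif, the gene of gastric intrinsic factor, at -2.65 ± 0.53 (adjusted p = 0.115 for each of the other 3). Without the first, second or the third array of 1/5, 8, 8699 and 1 genes passed, and 1 passed without the third array of concentration 1. Igtp passed in 9 of 20 alternatives, with an adjusted p of 0.00221 to 1.00.

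Between 1/5 and 1/25 at 24 h, TC566397, a transcript described as the membrane protein mKirre, was lower at 1/5, at -6.53 ± 0.68 (SD, n = 3) against -3.33 ± 0.41 (SD, n = 3), a difference of -3.20 ± 0.40 (SE, adjusted p = 0.0119) and at least 4.61-fold. Its probe lies on chromosome 8 from 34757610 to 34768638, and it was named after its values were seen. Gja4, a connexin gene of arterial endothelium, was at -1.90 ± 0.29 (adjusted p = 0.0600), Nefm, a neurofilament gene, at -1.59 ± 0.31, Grid1 at 1.94 ± 0.38 (at least 1.45-fold higher) and Ttbk1 at 1.75 ± 0.34 (adjusted p = 0.232 for each of the other 3). TC566397 was the 1 gene past the threshold, with 1996 at an unadjusted p under 0.05. It was lost without the second or the third array of 1/25 (adjusted p = 0.0786 and 0.0904). The count was 16 without the first array of 1/5, 4 without the second and 2 without the first array of 1/25. On the slide with 3 arrays of 1/5 and 1 of 1/25 the TC566397 difference was -2.73 (adjusted p = 1.00, with 1 array on one side and so little power), and with slide or scan day as a fixed block -2.73 (adjusted p = 0.369 and 0.265). Its adjusted p over 22 alternatives ran from 0.000355 to 1.00, and the median difference of all genes was 0.16.

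Between 24 h and 6 h at concentration 1, Akr1c15 and Akr1c14, both aldo-keto reductase genes on chromosome 17, and Igtp were higher at 24 h. Akr1c14, described as 3-alpha-hydroxysteroid dehydrogenase, was at -4.67 ± 0.94 (SD, n = 3) against -8.13 ± 0.41 (SD, n = 3), a difference of 3.45 ± 0.68 (SE, adjusted p = 0.0442) and at least 3.15-fold. Igtp was at -4.54 ± 0.70 (SD, n = 3) against -7.98 ± 0.28 (SD, n = 3), a difference of 3.45 ± 0.44 (SE, adjusted p = 0.00316) and at least 3.47-fold. Akr1c15 was at -0.26 ± 0.28 (SD, n = 3) against -2.53 ± 0.04 (SD, n = 3), a difference of 2.28 ± 0.39 (SE, adjusted p = 0.0260). Lower at 24 h were Cdh9, a cadherin gene, by -5.49 ± 0.95 (SE, adjusted p = 0.0260) and at least 15.3-fold, Ehmt1, a histone methyltransferase gene, by -5.08 ± 1.02 (adjusted p = 0.0495), and Elovl5, a fatty acid elongase gene, by -4.96 ± 1.00 (adjusted p = 0.0495).

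The Akr1c14 probe lies from 77327921 to 77327980 on chromosome 17, Igtp on chromosome 10 from 43865662 to 43865721, Cdh9 on chromosome 2 from 66859522 to 66859581, Ehmt1 on chromosome 3 from 3075647 to 3075706 and Elovl5 on chromosome 8 from 82961485 to 82961544. In all, 73 genes passed, 17 higher and 56 lower, and 4194 had an unadjusted p under 0.05. The comparison sets treated cultures at 24 h against treated cultures at 6 h, with no untreated group for either time. Time in culture and any effect of diclofenac cannot be told apart in it. No slide or scan day held both groups, so the same holds for time and slide.

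Igtp passed with each of the 6 arrays left out. Akr1c14, Cdh9 and Ehmt1 did not pass with any 1 of them left out, with adjusted p of 0.05004 to 0.251, 0.0625 to 0.120 and 0.0615 to 0.242. Akr1c15 passed only without the first array at 24 h (0.0811 to 0.122 without the others) and so did Elovl5 (0.0955 to 0.251). The count was 24, 16 and 12 without the first, second and the third array at 6 h and 34, 9 and 9 without those at 24 h. It was 477 (166 higher) without the third array of 1/5 for 24 h, a low-signal array of neither group that enters the shared spread, and 319 (204 higher) after quantile normalization.

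At concentration 1/5, Akr1c15 was again higher at 24 h than at 6 h, at 0.68 ± 0.97 (SD, n = 3) against -2.35 ± 0.16 (SD, n = 3), a difference of 3.03 ± 0.39 (SE, adjusted p = 0.00455). Thbd, which encodes thrombomodulin, the endothelial thrombin receptor, was at 1.10 ± 0.77 (SD, n = 3) against -0.87 ± 0.33 (SD, n = 3), a difference of 1.97 ± 0.34 (SE, adjusted p = 0.0383). Or13a26b, an olfactory receptor gene, was higher by 1.54 ± 0.26 (adjusted p = 0.0383). Chrnb1 was lower at 24 h, at -7.30 ± 0.61 (SD, n = 3) against -3.92 ± 0.43 (SD, n = 3), a difference of -3.38 ± 0.39 (SE, adjusted p = 0.00241) and at least 3.05-fold. Nptxr, a neuronal pentraxin receptor gene, was lower by -2.87 ± 0.52 (adjusted p = 0.0419) and Fgl2, which encodes a fibrinogen-like prothrombinase, by -2.55 ± 0.45 (adjusted p = 0.0406), at least 3.17-fold.

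The probes lie on chromosome 3 from 137064542 to 137064601 (Thbd), chromosome 1 from 200979442 to 200979501 (Or13a26b), chromosome 10 from 56619813 to 56620203 (Chrnb1), chromosome 7 from 118058187 to 118058246 (Nptxr) and chromosome 4 from 9177878 to 9177937 (Fgl2). In all, 30 genes passed, 15 in each direction, with 10061 at an unadjusted p under 0.05, and slide and time were again confounded. Chrnb1 passed with each of the 6 arrays left out and Akr1c15 without all but the first array at 6 h (adjusted p = 0.0606). Thbd was lost without the first, second or the third array at 6 h (0.178, 0.0759 and 0.132) and Or13a26b without these (0.178, 0.0954 and 0.123) or the first at 24 h (0.0570). Nptxr and Fgl2 passed only without the second array at 24 h, with adjusted p of 0.0808 to 0.188 and 0.0629 to 0.175 without the others. The count was 2, 8 and 9 without the first, second and the third array at 6 h and 31, 11684 and 16 without those at 24 h. When only the arrays of the 2 groups were in the fit 0 passed, and after quantile normalization 207 did (151 higher).

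**Figure D3:**
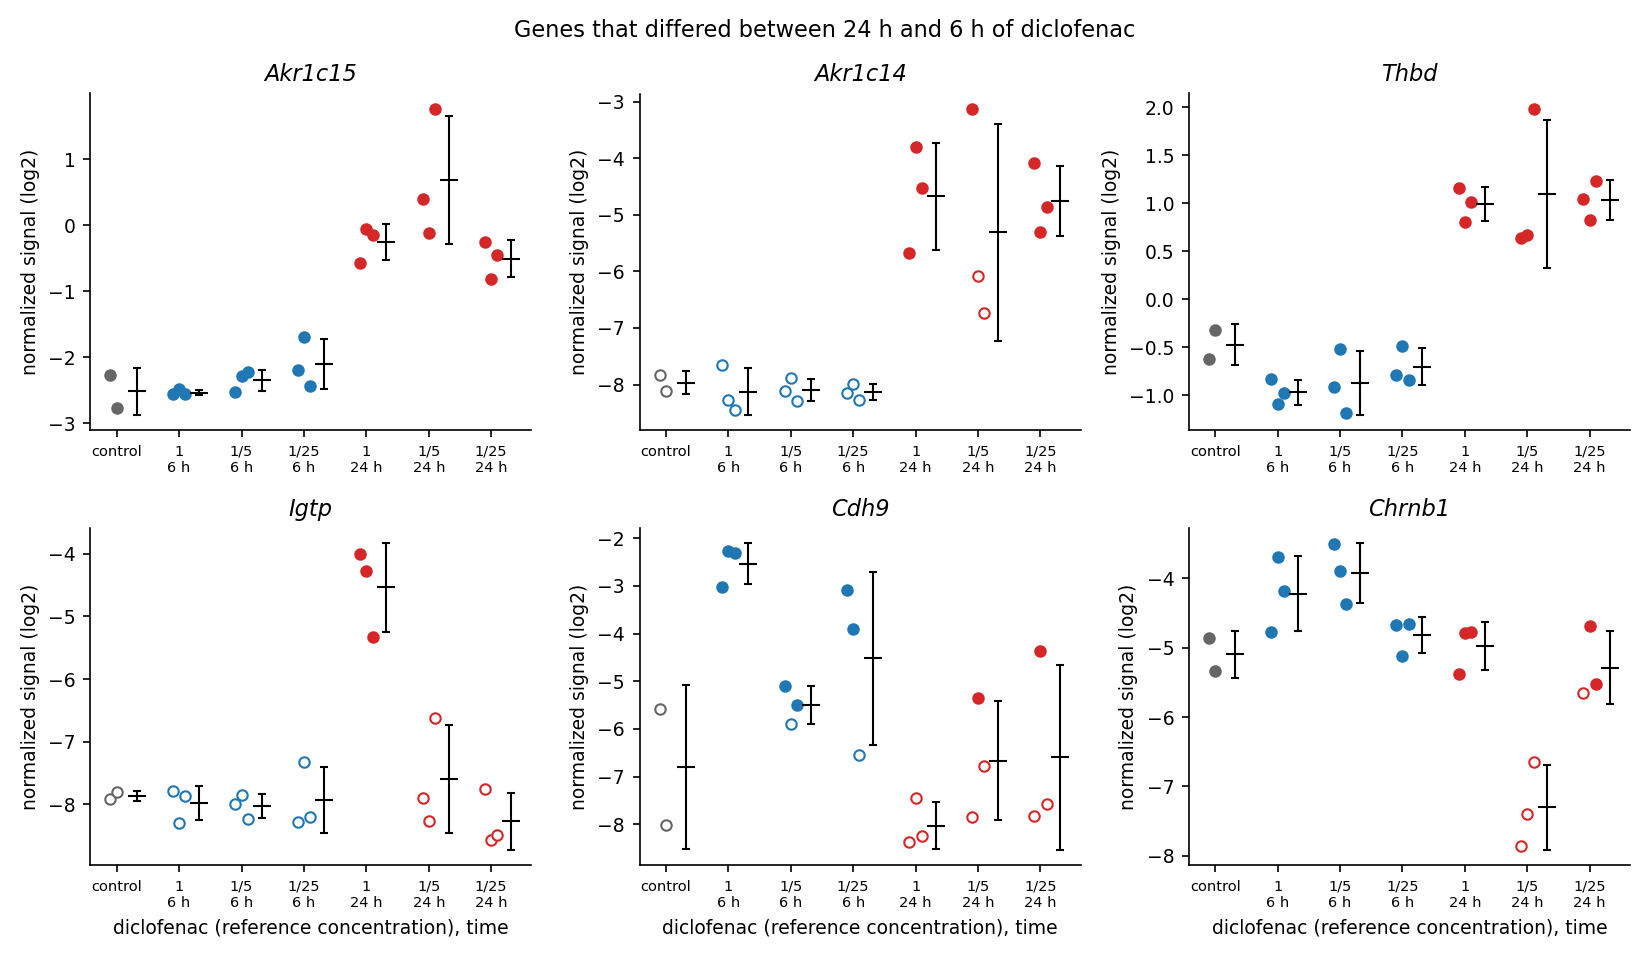
Normalized signal (log2) of 6 genes on each array by group, with filled points well above background, open points not, and black lines with bars the mean ± SD (n = 2 untreated, n = 3 otherwise). Akr1c15 lay between -0.50 and 0.68 in the 3 groups at 24 h and between -2.53 and -2.10 in the other groups.

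At concentration 1/25 limma called 0 genes between 24 h and 6 h, with 3024 at an unadjusted p under 0.05. The values at the smallest p were 1.74 ± 0.34 (SE) for Thbd, at 1.03 ± 0.21 (SD, n = 3) against -0.70 ± 0.19 (SD, n = 3), 2.26 ± 0.43 for Aldh1a4, an aldehyde dehydrogenase gene (at least 4.19-fold higher), -2.38 ± 0.42 for Os9 and -1.73 ± 0.31 for Adra2b, an adrenergic receptor gene (adjusted p = 0.132 each). Akr1c15 was at 1.60 (adjusted p = 0.273) and Akr1c14 at 3.38 (adjusted p = 0.137), at least 2.60-fold higher, in the same comparison. Without the second array at 24 h 537 genes passed, and without the third array of 1/5 for 24 h 87 did. With scan day as a fixed block 109 passed (7 higher), and on the scan day that holds 1 array at 24 h and 3 at 6 h, again with 1 array on one side, 0 did.

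The test of whether the difference between concentrations 1 and 1/25 itself differed between 24 h and 6 h called 0 genes with limma, with 787 at an unadjusted p under 0.05. Igtp was at 3.79 ± 0.62 (SE, adjusted p = 0.192), Atg12, an autophagy gene, at 2.69 ± 0.70 (adjusted p = 1.00), Gjb6, a connexin gene, at -3.81 ± 0.62 (adjusted p = 0.192) and Rhag at -4.66 ± 0.80 (adjusted p = 0.206). At 24 h Igtp was well above background on all 3 arrays of concentration 1 and on none of 1/5, 1/25 or the untreated cultures.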

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

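The tests of low signal on single arrays, of duration of treatment and of probe GC content as the whole cause were chosen after the results were seen. Results stand here because cultures treated for 24 h differed from those treated for 6 h at the same concentration in a direct test. There is no untreated group for each time, so these differences hold time in culture and slide as well as any difference in the effect of diclofenac. At concentration 1, 73 genes differed between 24 h and 6 h. Among them Akr1c14 differed by 3.45, Igtp by 3.45, Akr1c15 by 2.28, Cdh9 by -5.49, Ehmt1 by -5.08 and Elovl5 by -4.96 on the log2 scale. At concentration 1/5, 30 genes differed. Among them Akr1c15 differed by 3.03, Thbd by 1.97, Or13a26b by 1.54, Chrnb1 by -3.38, Nptxr by -2.87 and Fgl2 by -2.55.

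The same arrays were also split in every other way into groups of 3. For 24 h against 6 h at concentration 1 the real split gave 73 genes and the highest other split 0, and 1 of 10 splits gave as many. At concentration 1/5 these values were 30, 1 and 1 of 10. For concentration 1 against 1/5 at 6 h they were 2, 0 and 1 of 10. For 1/5 against 1/25 at 6 h and for 1 against 1/5 at 24 h the real and the highest other split gave 0, so 10 of 10 gave as many. With 10 splits no share under 0.05 can be reached. For 1/5 against 1/25 at 24 h the real split gave 1 gene, the highest other split 4793, and 5 of 10 gave as many. At concentration 1/25 the split of 24 h and 6 h gave 0 genes, the highest other split 5441, and 10 of 10 gave as many. Splits that call many times more genes than the real one point to a structure of the samples other than the groups. For the interaction of concentration and time the real split gave 0, the highest of 30 splits 1, and 30 of 30 gave as many. Where the real count is 0 every split gives as many, so those splits say nothing about chance.

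That structure was weighed as a pattern: 50.3% of the variance between arrays lay on 1 axis that crosses the groups. Low signal on single arrays may be its cause, since within groups the arrays' place on the axis followed their share of spots well above background (r = -0.883). Axis and share come from the same spot signals, so r cannot tell low signal as the cause from low signal as a sign of another cause. The sign of r follows from the direction set for the axis. The split with 4793 genes set the first and the third arrays of 1/5 and the first of 1/25 at 24 h, with 76.5, 64.1 and 72.4% of spots well above background, against the rest. Probe GC content as the whole cause is argued against: a GC correction took the rho between the loadings of genes and GC content from -0.287 to a size of 0.02 and left 97.4% of the variance of the axis (96.5 to 97.8% with 1 array left out). A part of GC content in the axis stays open. Duration of treatment, 1 of the biological factors in the design, also stays open with a share of 0.404 of the axis' variance. This value decides neither way, and 1 of the 6 slides held both times. Concentration, and treatment against no treatment, were not tested as causes of the axis.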

How the results depend on the processing

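The alternatives that leave out the third array of 1/5 for 24 h, weight the arrays, correct for probe GC content, block on scan day, or fit within a scan day or within the slides of treated groups only were chosen after the results were seen. Counts below are genes past the threshold, and a comparison not named under a setting kept a count within 1.5 times of its main one. A kept count need not hold the same genes. At 1 for 6 h, quantile normalization and slide as a fixed block each gave 2 genes, as in the main fit, but Rhag lost its call. At 1 for 24 h, a fit of only the groups compared gave 1 gene, which was higher, and AI168935 lost its call. Where a count moved the cause was not tested, except that a fit of fewer arrays has fewer degrees of freedom. The 25 named gene results past the threshold were run under 480 alternatives in all: 290 kept the call, 189 kept the direction and lost it, and 1 reversed. That was Rhag at concentration 1 for 6 h, which read -0.16 (adjusted p = 1.00, range over its alternatives 0.000458 to 1.00) with no filter on dim probes, since a brighter probe that the filter removes then stands for the gene. Of the 25 results, 18 kept their call in more alternatives than they lost it. The 213 results of named genes that did not pass kept that side and moved by less than the spread of replicates in 3830 alternatives, passed in 238 and moved by more in 148. Signal over background sets a limit too: the shared spread includes the array with 64.1% of spots well above background.

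With normexp background correction, 0 genes passed at concentration 1 for 6 h against untreated cultures, 1 between 1 and 1/5 at 6 h, 0 between 1/5 and 1/25 at 24 h, 125 (19 higher) between the times at 1, and 56 (32 higher) at 1/5. With quantile normalization, 6 passed at 1/25 for 24 h, 3 between 1 and 1/5 and 3 between 1/5 and 1/25 at 24 h, and 319 (204 higher), 207 (151 higher) and 9 between the times at 1, 1/5 and 1/25. With no filter on dim probes, 1 passed at 1 for 6 h, 0 at 1 for 24 h and 2 between 1 and 1/5 at 24 h, and with the mean of a gene's probes 3 at 1 for 24 h. A trended and robust fit gave 0 at 1 for 6 h, 0 at 1 for 24 h and 0 at 1/25 for 24 h. With only the groups compared in the fit, 4 passed at 1 for 6 h, 0 at 1/5 and 0 at 1/25 for 24 h, 0 between 1/5 and 1/25 at 24 h, and 2542 (832 higher) and 0 between the times at 1 and 1/5.

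With the authors' deposited table, whose scaling moved the median of all genes to 0.11, 0.40 and 0.37 at 24 h for 1, 1/5 and 1/25, 1 gene passed at 1 for 6 h, 2 at 1 for 24 h, 19 (9 higher) at 1/5 and 0 at 1/25 for 24 h, and 27 between the times at 1. Between the times at 1/5 it gave 23 (19 higher). With slide as a random block (estimated correlation -0.167), 65, 10398 and 65 passed at 24 h for 1, 1/5 and 1/25, 10 and 2 between adjacent concentrations at 6 h, 9536 and 5 at 24 h, 979, 13957 and 24 between the times, and 12 for the interaction. A negative correlation lowers the SE of a group whose arrays all lie on 1 slide, as for 1/5 at each time. The counts of this setting may therefore be too high, and they are no reading of a slide effect. With slide as a fixed block, 2 passed at 1/5 for 6 h, 7 between 1 and 1/5 at 6 h and 0 between 1/5 and 1/25 at 24 h. Within the slide that holds both groups, 0 passed at 1 for 6 h, 0 between 1 and 1/5 at 6 h and 0 between 1/5 and 1/25 at 24 h, the last 2 with 1 array on one side. With scan day as a fixed block, 1 passed at 1 for 6 h, 6 between 1 and 1/5 and 3 between 1/5 and 1/25 at 24 h, and 109 between the times at 1/25.

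With the replicate block, which the arrays' deviations gave no clear ground for but did not exclude, 1 gene passed at 1 for 6 h, 0, 21 and 0 at 24 h for 1, 1/5 and 1/25, and 26 and 8 between the times at 1 and 1/5.

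Without the third array of 1/5 for 24 h, 4 genes passed at 1 for 6 h, 24 and 79 at 24 h for 1 and 1/25, 8 and 1 between adjacent concentrations at 6 h, 1 between 1 and 1/5 at 24 h, 477, 16 and 87 between the times at 1, 1/5 and 1/25, and 2 for the interaction. Array weights by REML ran from 0.000324 to 1479 and so rest the fit on few arrays. They gave 70, 534 and 4 genes at 6 h and 9023, 0 and 20247 at 24 h for 1, 1/5 and 1/25, 8584 and 5580 between adjacent concentrations at 6 h, 0 between 1/5 and 1/25 at 24 h, 18534, 0 and 22310 between the times and 15864 for the interaction. Weights estimated gene by gene ran from 0.0388 to 8.12. They gave 44 and 51 at 6 h for 1 and 1/5, 4323, 11457 and 15087 at 24 h, 3410 and 993 between adjacent concentrations at 6 h, 6936 and 64 at 24 h, 13627, 10468 and 17411 between the times and 5266 for the interaction. With GC correction, 1 passed at 1 for 6 h, 3 and 2 at 24 h for 1 and 1/25, 1 between 1 and 1/5 at 24 h, and 109 and 1 between the times at 1/5 and 1/25. The list tests called 1 list, the proteasome subunit genes at 1/25 for 24 h, with REML weights (adjusted p = 0.0371) and with GC correction (adjusted p = 0.0198), and 0 under the other settings of camera and with fry.

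With 1 array left out at a time, counts at 6 h ran from 0 to 2 for concentration 1 and were 0 to 0 for 1/5 and 1/25. At 24 h they ran from 0 to 1, 0 to 10783 and 0 to 617. Between adjacent concentrations they ran from 1 to 2 and 0 to 16 at 6 h and from 0 to 8699 and 0 to 16 at 24 h. Between the times they ran from 9 to 34, 2 to 11684 and 0 to 537. For the interaction and the list tests they were 0 to 0. With an untreated array left out, the lone one left is assumed to vary like the other groups, and limma then called 0 genes in each comparison with untreated cultures. The highest counts at 24 h came without the second array of 1/5 (10783, 8699 and 11684) or of 1/25 (617 and 537).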

Other observations

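The test of a family-wide increase was chosen after the result was seen. Probes described as spindlin-like, a family of chromatin-binding proteins to which LOC291521 belongs, were higher at concentration 1 for 6 h. Of 51 such probes 48 were higher than in untreated cultures, 21 of them by more than 2 (log2), with a median of 1.71. On every array of that group 44 were well above background, against 18 on both untreated arrays. At 6 h the median was 0.34 at 1/5 and -0.01 at 1/25, at percentiles 99.99 and 99.18 among 10000 random probe sets matched on the untreated signal. At 24 h it was -0.39, -0.10 and -0.31 for 1, 1/5 and 1/25, at percentiles 43.7, 41.8 and 95.8. Whether the family as a whole rose stays open: at concentration 1 for 6 h the median lay at percentile 100 among such sets, but the probes were put together after they were seen to rise there, so this gives no support. The percentile was also high at the other 2 concentrations for 6 h, so it does not single out concentration 1, while the median was largest there. Whether 1 transcript, or DNA of a family with many copies, bound many of these probes was not tested, and no biological explanation was tested beyond the concentration itself.

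In the same group 178 genes were higher by more than 2 and 10 lower. Of the 178, 84 (47.2%) were well above background on neither untreated array, against 1.74% of all genes. Both shares depend in part on the filter on dim probes. The 178 were also picked by a rise that favours genes dim in untreated cultures, so the gap between the shares is no result by itself. At 1/5 for 6 h 36 genes were higher by more than 2 and 34 lower, and at 1/25 for 6 h 14 and 40. Scaling between arrays as the whole cause is argued against by the ratio of genes higher to genes lower after quantile normalization, 9.06, and slide as the whole cause by the lower of the ratios within 2 slides, 12.1. This was on the slide with 2 arrays of the group and both untreated arrays, and the other slide, at 13.2, set 1 array of the group against 3 of 1/5 and not against untreated cultures. Signal over background of the arrays was not tested as a cause and stays open. At 24 h more genes were lower by over 2: 444 against 85 higher at 1, 2307 against 536 at 1/5 and 1483 against 105 at 1/25. The arrays of concentration 1 for 6 h had 84.5, 85.9 and 88.2% of spots well above background. The untreated arrays had 82.5 and 84.7%. Genomic DNA in the labelled RNA stays open as a possible explanation: 1170 probes of olfactory and vomeronasal receptors, taken as a reading of DNA, had a median of 0.12, at percentile 99.61 among matched random sets. Of these probes 461 were well above background on both untreated arrays, so some may read RNA of the cultures. That median is far below 2, and at 1/5 for 6 h the same probes lay at -0.07, below all random sets, so shifts of this size also occurred downward.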
